A study of Mus musculus with 17 samples.

How the data were processed

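The series holds 17 expression arrays, each hybridised with total RNA from cells sorted from the cortex of hGFAP-eGFP mouse embryos. Per the labels, RNA was isolated with an RNeasy kit with DNase treatment on the column and labelled with biotin. The values used are the intensity values of 45101 probe sets as deposited, already processed by the authors to 1 linear signal per probe set. The summarisation software, its version and the scaling target are not given in the sources used here. The values run from 0.0397 to 59926, and the mean of the values between the 2nd and 98th percentiles is 150.0 on every array, as after a global scaling of each array. The median signal per array was 24.2 to 45.1, and 0 pairs of arrays were identical. The number of arrays limits the precision.

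Samples were grouped by the age, GFP gate and Prominin gate in their labels into 5 groups: E14 GFP-high Prominin-selected (n = 4), E14 GFP-low Prominin-selected (n = 3), E14 GFP-high (n = 3), E14 GFP-low (n = 3) and E18 GFP-positive Prominin-selected (n = 4). The labels of the groups written without Prominin name no Prominin gate. The labels name a MessageAmp II labelling kit for the 11 Prominin-selected arrays and ungated E14 GFP-high replicate 1, and an Affymetrix kit for the other 5 arrays. The labels do not say that the samples came from separate litters. Replicate numbers are shared between groups, but correlations between arrays with the same number, after group means were removed, were −0.144 to 0.040, so the numbers were not taken as pairs.

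The analysis used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9 for the figures. After 64 control probe sets were left out, 45037 remained: 34945 carried 1 gene symbol, 932 several symbols and 9160 no listed gene. The probe sets with 1 symbol were kept, and 34741 of them matched a RefSeq gene table for GRCm38.p6 by Entrez identifier, with 0 symbols updated. For the 9010 of 18193 genes with more than 1 probe set, the probe set with the highest mean was used. Values were transformed to log2 after a pseudocount of 16 was added and then normalised by quantiles across the 17 arrays. That normalization followed a rule fixed beforehand, since array medians differed by 0.602 on the log2 scale and the largest difference allowed for values as deposited was 0.5. Fold changes on this scale understate those of dim genes and depend on the pseudocount, whose log2 is 4, against a median gene level of 6.29.

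There were 7 comparisons: GFP-high minus GFP-low at E14 with the Prominin gate and without it, E18 minus either E14 Prominin-selected group, gated minus ungated cells at either GFP level, and the gated minus the ungated GFP contrast. Contrasts among Prominin-selected groups were fitted on those 11 arrays, the ungated GFP contrast on its 6 arrays and the others on all 17. Genes were tested with limma's moderated statistics (eBayes, two-sided) and called changed at a Benjamini-Hochberg adjusted p under 0.05. Of 28 fixed gene lists 27 were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and sex-linked genes were only described. Adjusted p of lists are over the 27 lists of a comparison, and counts adjusted over the list alone use the gene p-values of its members. The p-values measure only the spread between these samples, which may be technical. Single values were compared by exact permutation.

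The comparisons, gene lists, tests, normalization rule, alternative settings and the rule for named genes were set before the data were examined. Named genes were Prom1, Gfap, Slc1a3, Fabp7, Pax6, Eomes, Tfap2c and Tubb3 whatever their result, then the largest rises and falls among called genes. These were 8 of each for the GFP contrasts and E18 against E14 GFP-high cells, and 5 of each elsewhere. They needed groups that did not overlap, except in the difference of contrasts, and a higher group mean above the median of all genes. To these came up to 4 members of each list with the lowest p among those past the threshold, or up to 2 members where a list had none. The text names only a part of these genes, mostly those whose call was kept in the alternatives run, and that choice was made after their values were seen. Called probe sets of the same gene went in opposite directions for H2-D1, Nfia and Lss at E18 against E14 GFP-high cells and for Pax6 and Papola at E18 against GFP-low cells. They also did so for Ncan and Zbtb20 between gated and ungated GFP-high cells and for Gli3, Pax6, Numb and Slc1a3 between gated and ungated GFP-low cells. Named genes could also have probe sets that were not called. For Rpl27a and Reln, 1 of 2 probe sets was called between gated and ungated GFP-low cells.

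The procedure was tested on simulated data with the same group sizes, in which 200 genes were shifted. At a log2 shift of 0.5, 1 and 2, the calls recovered 5.97%, 47.8% and 86.4% of genes in the gated GFP contrast and 0%, 5.97% and 50% in the ungated one. They recovered 4.48%, 49.3% and 97.0% for E18 against GFP-high cells, and 8.96%, 47.8% and 90.9% for E18 against GFP-low cells. Between gated and ungated cells they recovered 7.46%, 49.3% and 90.9% at high GFP and 1.49%, 38.8% and 89.4% at low GFP, and for the difference of contrasts 0%, 16.4% and 60.6%. False calls made up 6.06%, 7.5%, 3.85%, 7.55%, 5.77%, 4.44% and 12.1% of calls in the same order, and 0 had the wrong sign. With no list shifted, camera called 0 lists in every comparison but the difference of contrasts, where it called 1, and a shifted list was called in all 7. Simulated genes were drawn independently of each other, so these runs do not show how camera behaves where genes are correlated. Recovery after the adjustment also depends on the share of genes that change. That share was 200 of 18193 here, whereas 305 to 4850 genes were called in the data, so these rates are not those of the real contrasts.

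The alternatives were values as deposited, median centring, pseudocounts of 1 and 64, leaving out the dimmest 40% of genes, the mean of a gene's probe sets, every probe set by itself, an intensity trend, robust eBayes, array weights, a log2 fold change of at least 1, other sets of arrays in the fit, the replicate number as a block, the kit as a term, and leaving out each array in turn. Leaving out an array kept the normalised values and dropped it from the fit. Leaving out arrays with unusual control values, correlations or kit labels was added after the data had been seen. Probe sets with several or no symbols and the control probe sets were not used in the comparisons.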

Results

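Gene expression was measured in cells sorted by flow cytometry from the cerebral cortex of hGFAP-eGFP mouse embryos, in which a human GFAP promoter drives green fluorescent protein (GFP) in radial glia, the neural stem and progenitor cells of the developing cortex. Each of 17 samples of total RNA was hybridised to 1 Affymetrix mouse expression array. At embryonic day 14 (E14), GFP-high (n = 4) and GFP-low (n = 3) cells were also selected for Prominin, the membrane protein encoded by Prom1. GFP-high (n = 3) and GFP-low (n = 3) cells of the same age carry labels that name no Prominin gate and are called ungated here. At embryonic day 18 (E18), GFP-positive Prominin-selected cells made up the fifth group (n = 4). The series title concerns subtypes of radial glia, so the contrasts between GFP-high and GFP-low cells, between ages and between gated and ungated sorts are described in turn. Levels are log2 intensities, given as mean ± SD over the arrays of a group, and fold changes carry a standard error on the log2 scale. The median level of all 18193 genes was 6.29, and the number of arrays limits the precision. Where the lower group lay at or below 5.77, the highest group mean of Gfap, its signal is not shown to be above background. There no fold is given, only levels or the log2 fold change, whose size depends on the pseudocount. The labels do not say that the samples came from separate litters, so p-values measure only the spread between these samples, which may be technical.

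The E14 Prominin-selected arrays differed from the others in their control signals, most clearly in 18S. The 3′ minus 5′ difference of the Gapdh control was 0.54 to 2.29 on these 7 arrays, against −0.25 to 0.18 on the ungated arrays and −0.21 to 1.00 on the E18 arrays. The signal of an 18S ribosomal RNA control was 2292 to 5192 on the E14 Prominin-selected arrays, against 175 to 627 ungated and 302 to 583 at E18. The dap poly-A control, a transcript usually spiked in before labelling, read 3.85 to 22.3 on 6 of the 7 E14 Prominin-selected arrays and 4085 on GFP-high replicate 1. Contrasts with E18 or with ungated cells cross this difference. The contrast within the E14 Prominin-selected arrays holds a part of it, in the dap signal of GFP-high replicate 1. The Gapdh differences of GFP-high replicate 1 (0.54) and GFP-low replicate 2 (0.920) lay within the range at E18.

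**Figure D1:**
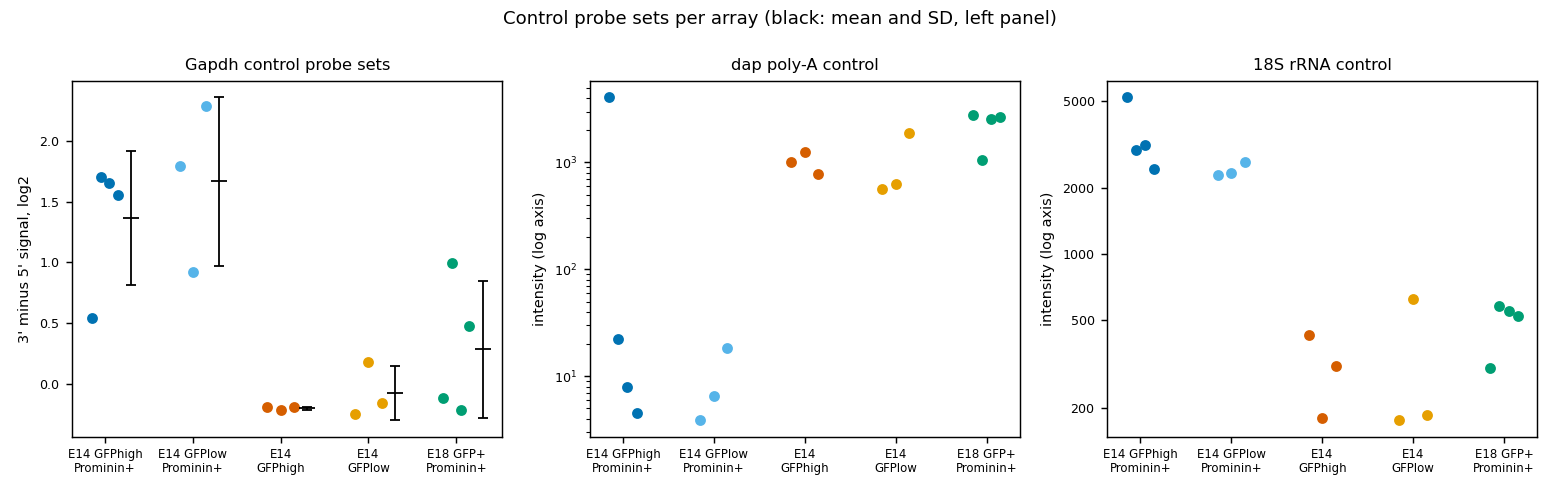
Control measures on each of the 17 arrays, grouped by sort: the 3′ minus 5′ difference of Gapdh (log2), the dap poly-A signal and the 18S signal (intensity, log axes), with 1 point per array. The 7 E14 Prominin-selected arrays have 18S signals of 2292 to 5192, above all other arrays, and all but 1 of them have dap signals of 22.3 or lower.

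The question of how radial glia with high and low GFP differ was addressed within a gate on Prominin, a protein of the apical membrane. Among Prominin-selected cells at E14, GFP-high cells had more Prom1 mRNA than GFP-low cells, by 1.67-fold (log2 fold change 0.74 ± 0.14, 10.93 ± 0.09 against 10.19 ± 0.08, adjusted p = 0.0309). Gfap itself lay below the median gene level in both, at 5.42 ± 0.26 and 5.10 ± 0.79 (adjusted p = 0.743). Neurog1, a proneural transcription factor, was 2.79-fold higher in GFP-high cells (1.48 ± 0.21, adjusted p = 0.00793). Sox3, a transcription factor of neural progenitors, was 2.31-fold higher (1.21 ± 0.18, adjusted p = 0.00796), and the Wnt receptor gene Fzd8 was 2.30-fold higher (8.29 ± 0.10 against 7.09 ± 0.19, adjusted p = 0.00594). The largest fall was in Reln, which encodes the glycoprotein secreted by Cajal-Retzius neurons: it was 6.94-fold lower in GFP-high cells (−2.80 ± 0.25, 9.02 ± 0.23 against 11.82 ± 0.21, adjusted p = 0.000928). Rspo3, which encodes a secreted enhancer of Wnt signalling, was 3.71-fold lower (−1.89 ± 0.17, adjusted p = 0.000928), and Dact1 was 3.22-fold lower (adjusted p = 0.00225). The desmosomal gene Dsp was at 5.16 ± 0.18 against 6.86 ± 0.26 (−1.70 ± 0.18, adjusted p = 0.00225).

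Genes of the Cajal-Retzius list were lower together in GFP-high cells: 5 of 8 fell, 7 when adjusted over the list alone, with a median of −1.15 (camera adjusted p = 2.11e-12). Besides Reln, Lhx1 was lower (−1.96 ± 0.27, 4.71 ± 0.52 against 6.67 ± 0.40), a call that ended with a pseudocount of 1 (adjusted p = 0.0713), and so was Ndnf (−1.67 ± 0.25, 4.88 ± 0.48 against 6.54 ± 0.03). Of the postmitotic neuron list, 7 of 21 fell, 13 adjusted over the list alone, with a median of −0.65 (adjusted p = 1.03e-13). They included Stmn2, a regulator of neuronal microtubules, at 3.32-fold lower (−1.73 ± 0.22), Ina at 2.57-fold lower (−1.36 ± 0.19) and the synaptic gene Snap25 at 2.42-fold lower (−1.27 ± 0.19). The radial glia list was higher, with 4 of 22 risen, 14 adjusted over the list alone, and a median of 0.71 (adjusted p = 1.45e-13). Of the basal progenitor list 1 of 16 rose, 6 adjusted over the list alone, with a median of 0.53 (adjusted p = 5.37e-08), and that gene was Neurog1. Eomes, the transcription factor that marks basal progenitors, was at 12.05 ± 0.04 and 11.49 ± 0.09 (adjusted p = 0.147). Among cell division genes, 6 of 19 of the G2/M list rose, 17 adjusted over the list alone, with a median of 0.72 (adjusted p = 6.93e-19). Of the S-phase list 1 of 21 rose, 11 adjusted over the list alone, with a median of 0.48 (adjusted p = 6.12e-12). The Notch list had 2 of 19 higher and 1 lower, with 6 higher and 1 lower adjusted over the list alone, and a median of 0.50 (adjusted p = 7.31e-06). The lower gene was Dner, a neuronal Notch ligand gene. The pallial patterning list had 2 of 12 higher, 4 adjusted over the list alone, and a median of 0.41 (adjusted p = 7.01e-05). These 8 lists held with an estimated correlation between genes, with adjusted p from 0.00646 to 0.0452.

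A further 3 lists were called only with the preset correlation. In the interneuron list 1 of 16 fell, also 1 adjusted over the list alone (median −0.39, adjusted p = 0.00492, adjusted p = 0.247 with an estimated correlation). The call ended without GFP-low replicate 3 (0.0622), also when GFP-high replicate 1 was left out with it (0.142). The gene that fell was Calb2, the calretinin gene, which Cajal-Retzius cells also express, at 5.20 ± 0.40 against 7.13 ± 0.47 (−1.94 ± 0.29). In the glycolysis list no gene rose and Pfkp fell, 1.92-fold (−0.94 ± 0.13), although the list median was 0.33 (adjusted p = 0.0153, adjusted p = 0.244 with an estimated correlation). Adjusted over the list alone, 1 of its 12 genes rose and 1 fell, and the call ended without GFP-low replicate 1 (0.0765) or 3 (0.0622). It also ended when GFP-high replicate 1 and GFP-low replicate 3 were both left out (0.136). The apical junction list had a median of 0.11 (adjusted p = 0.0318, adjusted p = 0.398 with an estimated correlation). Of its 15 genes 2 were higher, 5 adjusted over the list alone, and the atypical protein kinase C gene Prkcz was lower by either adjustment. This list call ended without GFP-high replicate 2 (0.0570), 3 (0.0981) or 4 (0.132), and without GFP-low replicate 1 (0.0639) or 3 (0.0622). It also ended without the dimmest 40% of genes (0.0759). The other 16 lists had medians from −0.30 to 0.28 and adjusted p from 0.0884 to 0.818: astroglial maturation, gliogenic factors, early temporal factors, oligodendrocyte lineage, Wnt, FGF, BMP, extracellular matrix and receptors, cholesterol synthesis, interferon and MHC, choroid plexus and hem, endothelial, pericyte and meninges, microglia and macrophage, erythroid, and immediate early and stress genes. In the Wnt list and the interferon list, the median and the test differed in sign.

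In all, 305 of 18193 genes changed, 87 higher and 218 lower in GFP-high cells, and 130 of them at least doubled or halved in level on the log2 scale. At an unadjusted p under 0.05 there were 2440, and 13.2% of all genes had groups that did not overlap, against 5.71% by chance. The number of genes depended on single arrays: it was 129, 109 and 76 without GFP-high replicates 1, 3 and 4, and 85, 90 and 78 without GFP-low replicates 1, 2 and 3. It was 6 when GFP-high replicate 1 and GFP-low replicate 3 were both left out, with Reln, Rspo3, Dact1 and Dsp among those still called. Of the 43 named genes called, 28 lost the call without at least 1 of the 7 arrays. That of Prom1 ended without any array except GFP-high replicate 2 (adjusted p 0.0538 to 0.0973), and those of Prkcz and Dner without any of the 7 (0.0531 to 0.155 and 0.0512 to 0.122).

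**Figure D2:**
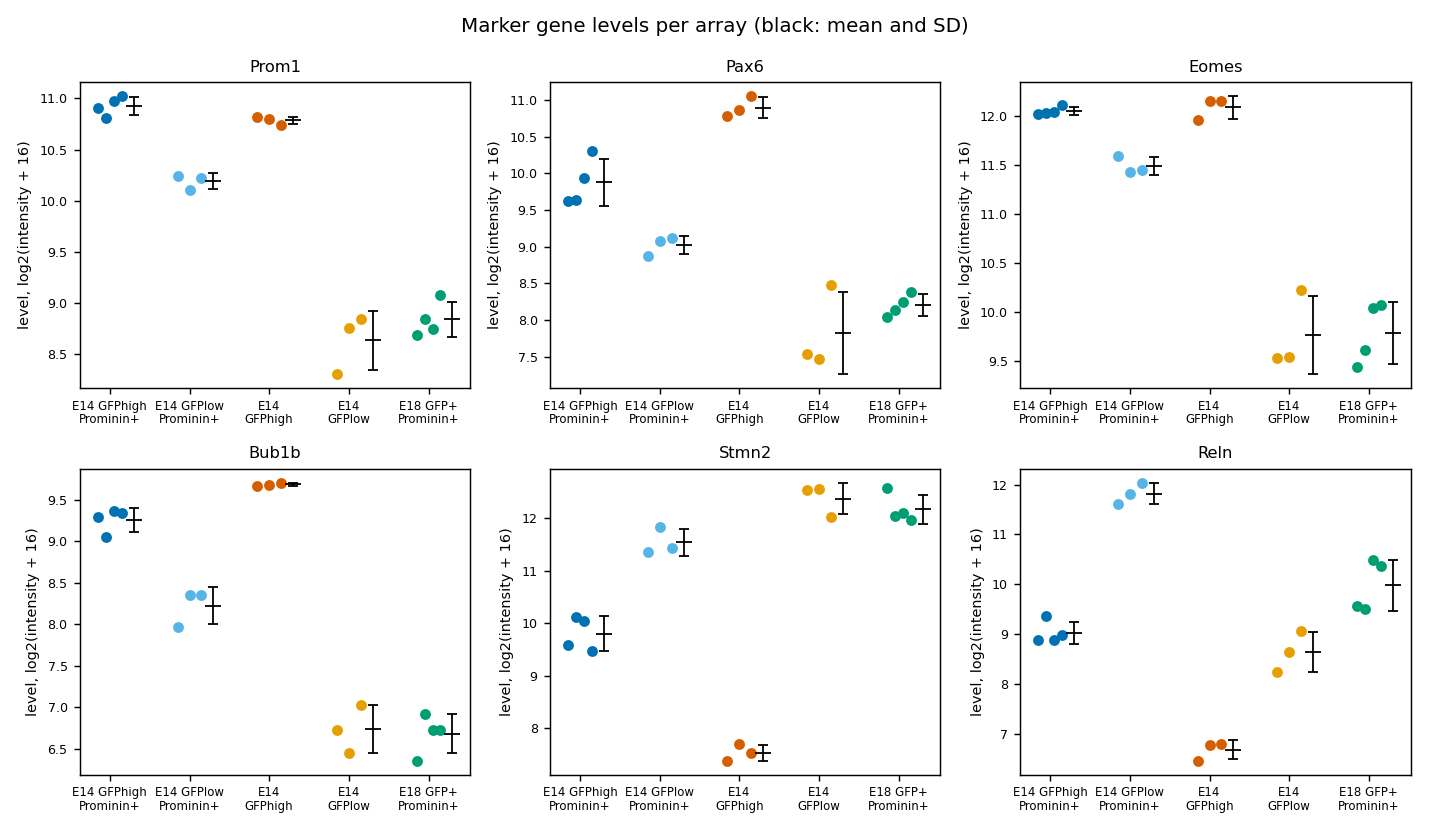
Log2 intensity of Prom1, Pax6, Eomes, Bub1b, Stmn2 and Reln on each of the 17 arrays in the 5 groups, with the group mean and SD. Reln lies at 11.82 ± 0.21 in the E14 GFP-low Prominin-selected group and at 9.02 ± 0.23 in its GFP-high counterpart.

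The same question was addressed without a named gate. In the ungated cells at E14, Prom1 was 4.45-fold higher in GFP-high than in GFP-low cells (2.15 ± 0.20, 10.79 ± 0.04 against 8.63 ± 0.29, adjusted p = 0.000918). Gfap was at 5.59 ± 0.36 and 4.82 ± 0.45 (adjusted p = 0.139). Of the 8 largest falls in GFP-high cells, 3 were in genes of the postmitotic neuron list. Stmn2 was 28.4-fold lower (−4.83 ± 0.21, 7.54 ± 0.15 against 12.37 ± 0.30), Ina 28.2-fold lower (−4.82 ± 0.34) and Mapt, which encodes the axonal protein tau, 25.8-fold lower (−4.69 ± 0.20). The largest fall, in Sla, was from 9.84 ± 0.34 to 4.78 ± 0.51 (−5.06 ± 0.31). The cortical progenitor gene Pax6 was 8.38-fold higher (3.07 ± 0.30, 10.89 ± 0.14 against 7.83 ± 0.56), the orphan nuclear receptor gene Nr2e1 8.52-fold higher (3.09 ± 0.22) and Eomes was higher by 2.32 ± 0.24 on the log2 scale.

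By group, 19 of 22 radial glia genes rose, also 19 adjusted over the list alone, with a median of 2.33 (adjusted p = 2.04e-15, adjusted p = 0.129 with an estimated correlation). They included Aldoc, at 7.85-fold higher, and Ednrb, at 6.71-fold. Of the basal progenitor genes 13 of 16 rose, 14 adjusted over the list alone, with a median of 1.84 (adjusted p = 1.62e-11, adjusted p = 0.0713 with an estimated correlation). All 19 G2/M genes and all 21 S-phase genes rose by either adjustment, with medians of 2.71 and 2.08 (adjusted p = 6.91e-20 and 1.23e-19, adjusted p = 0.143 and 0.129 with an estimated correlation). The mitotic checkpoint gene Bub1b was 7.71-fold higher (2.95 ± 0.20), and the replication helicase gene Mcm6 7.67-fold (2.94 ± 0.22). Of the postmitotic neuron list 19 of 21 fell, with a median of −2.35 (adjusted p = 2.52e-18, adjusted p = 0.0726 with an estimated correlation), and adjusted over the list alone 19 fell and 1 rose. The pallial patterning list had 8 of 12 higher, 9 adjusted over the list alone, and a median of 1.56 (adjusted p = 1.14e-06, adjusted p = 0.206 with an estimated correlation). The Notch list had 11 of 19 higher and 1 lower, 11 and 2 adjusted over the list alone, and a median of 1.2 (adjusted p = 3.20e-06, adjusted p = 0.130 with an estimated correlation). Notch1 was 7.82-fold higher, whereas Dner was 4.80-fold lower.

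The remaining 3 called lists held genes that moved both ways. The glycolysis list had 7 of 12 higher and 2 lower, 8 and 2 adjusted over the list alone, and a median of 0.78 (adjusted p = 0.00308, adjusted p = 0.129 with an estimated correlation), with Pfkp lower (−2.22 ± 0.24, 5.76 ± 0.26 against 7.98 ± 0.34). The apical junction list had 6 of 15 higher and 1 lower by either adjustment, and a median of 0.42 (adjusted p = 0.00326, adjusted p = 0.206 with an estimated correlation), with Celsr1 5.54-fold higher and Prkcz 4.76-fold lower. The astroglial maturation list had 5 of 21 higher and 2 lower, 7 and 2 adjusted over the list alone, and a median of 0.58 (adjusted p = 0.00583, adjusted p = 0.129 with an estimated correlation). Mlc1 was higher (2.95 ± 0.19, 7.40 ± 0.15 against 4.45 ± 0.21), whereas Sparcl1, an astrocyte matrix gene that neurons also express, was 4.15-fold lower. The Cajal-Retzius list was not called (median 0.00, adjusted p = 0.831), with Reln 3.91-fold lower (−1.97 ± 0.25). Ebf3 of the same list was higher (0.77 ± 0.20, 6.33 ± 0.29 against 5.56 ± 0.11, adjusted p = 0.0444). The 17 lists not called had medians from −0.39 to 0.81 and adjusted p from 0.0581 to 0.954, and in 5 of them the median, mean and test differed in sign, the Cajal-Retzius list among them.

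**Figure D3:**
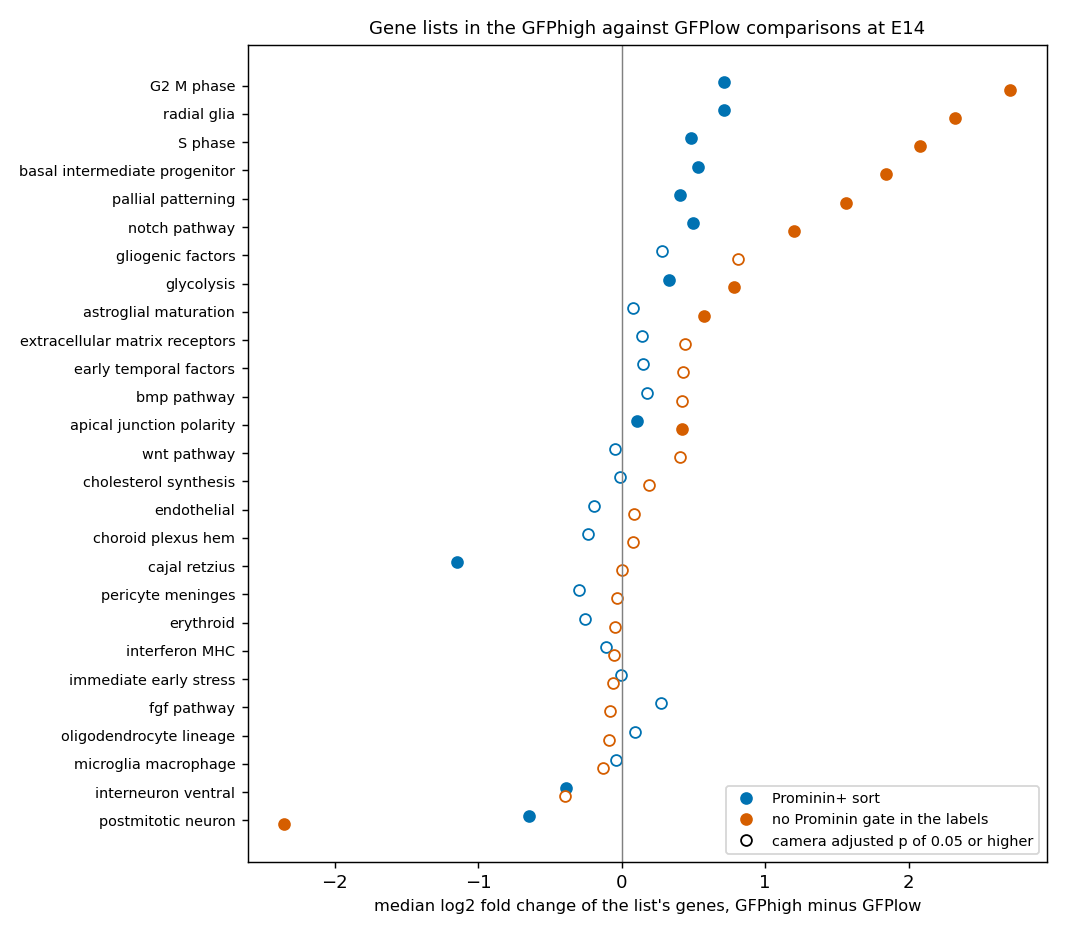
Median log2 fold change of GFP-high over GFP-low cells at E14 for 27 gene lists, with the Prominin gate and without a named gate. Filled points are lists with a camera adjusted p under 0.05 at the preset correlation and open points are the others. The G2/M list lies at 0.72 with the gate and 2.71 without, and the Cajal-Retzius list at −1.15 and 0.00.

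Of 18193 genes, 2869 changed between the ungated sorts, 1384 higher and 1485 lower in GFP-high cells, and 2111 of them at least doubled or halved. At an unadjusted p under 0.05 there were 5156, and 34.3% of all genes had groups that did not overlap, against 10% by chance. The count was 1841 without GFP-high replicate 1, the array whose labels name another labelling kit than the rest of its group, 1894 without GFP-high replicate 3, and 1257 without GFP-high replicate 1 and GFP-low replicate 2. The called lists were lost when the correlation between genes was estimated.

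The contrasts with and without the gate share no array, and they were set side by side. Of the 305 genes changed with the gate, 284 (93.1%) had the same sign without it. Independent lists would share 6.62 higher and 17.8 lower genes, against 75 and 183 observed, and 1 gene was called in opposite directions. Across all genes the fold changes correlated with r = 0.554 (rho = 0.433), where genes are not independent replicates. Over the 305 genes the median absolute log2 fold change was 0.96 with the gate and 2.28 without.

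The difference between these contrasts was tested directly, as the gated minus the ungated contrast. For Prom1 it was −1.42 ± 0.22 (adjusted p = 0.000966), and for Gfap −0.45 ± 0.47 (adjusted p = 0.686). The fall of Stmn2 and Mapt in GFP-high cells was smaller with the gate, by 3.10 ± 0.31 and 3.65 ± 0.30 on the log2 scale (adjusted p = 5.61e-05 and 1.85e-05). The rise of Pax6 was smaller with the gate (−2.22 ± 0.33, adjusted p = 0.000685), as was that of Eomes (−1.76 ± 0.28, adjusted p = 0.000966). The contrast in Calb2 differed the other way, towards a fall with the gate (−2.56 ± 0.49, adjusted p = 0.00355).

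By list, all 19 G2/M genes had a lower contrast with the gate by either adjustment (median −1.94, adjusted p = 1.66e-26), as had 19 of 21 S-phase genes, 20 adjusted over the list alone (median −1.71, adjusted p = 1.29e-23). Of the radial glia list 16 of 22 were lower, 19 adjusted over the list alone (median −1.59, adjusted p = 6.17e-19), and of the basal progenitor list 5 of 16, 12 adjusted over the list alone (median −1.10, adjusted p = 2.54e-09). The postmitotic neuron list was higher, with 14 of 21 genes, or 19 higher and 1 lower adjusted over the list alone (median 1.54, adjusted p = 5.10e-22). The Cajal-Retzius list was lower with the gate, as in the gated contrast itself, with 2 of 8 genes, 4 adjusted over the list alone (median −0.91, adjusted p = 7.10e-05). Those 2 were Lhx1 (−2.27 ± 0.46, adjusted p = 0.00492) and Ebf3 (−1.65 ± 0.28, adjusted p = 0.00144). Lower medians were also found for pallial patterning (−1.17), Notch (−0.80) and astroglial maturation (−0.45), with 6 of 12, 7 of 19 and 4 of 21 genes lower. Adjusted over the list alone these were 8, 10 and 7 genes (adjusted p = 3.54e-07, 7.31e-05 and 0.00246). The apical junction list, with 6 of 15 lower and 1 higher by either adjustment, lost its call (median −0.38, adjusted p = 0.000463, adjusted p = 0.123 with an estimated correlation), and the other 9 held. The 17 lists not called had medians from −0.55 to 0.26 and adjusted p from 0.0735 to 0.906, and in 3 of them the median, mean and test differed in sign.

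In total 1400 genes differed in contrast, 704 higher and 696 lower, with 3490 at an unadjusted p under 0.05. With 4 arrays left out for unusual control or correlation values or, for ungated GFP-high replicate 1, for its kit label, the count was 597. The 4 were GFP-high Prominin-selected replicate 1, GFP-low Prominin-selected replicate 3, ungated GFP-high replicate 1 and ungated GFP-low replicate 2. Without them the calls of Tfap2c (−1.65 ± 0.38, adjusted p = 0.0127 with all arrays, 0.0525 without the 4) and Lhx1 (0.0538) also ended.

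The change with age was followed from E14 GFP-high to E18 GFP-positive cells, both Prominin-selected. The E18 labels do not divide GFP into high and low, so contrasts with E18 differ in the GFP gate as well as in age. Prom1 was 4.26-fold lower at E18 (−2.09 ± 0.13, 8.84 ± 0.17 against 10.93 ± 0.09, adjusted p = 8.62e-07), and Gfap was at 5.77 ± 0.37 and 5.42 ± 0.26 (adjusted p = 0.455). Olig1, a transcription factor of the oligodendrocyte lineage, was at 10.61 ± 0.31 at E18 against 5.42 ± 0.21 at E14, a level like that of Gfap (5.19 ± 0.29, adjusted p = 4.90e-07). Its log2 fold change was 5.82 and 4.14 with pseudocounts of 1 and 64. Dlx1, a transcription factor of ventral forebrain progenitors and their interneurons, was 16.5-fold higher (4.04 ± 0.23), and the GABA receptor gene Gabra2 was at 9.07 ± 0.11 against 5.69 ± 0.09 (3.38 ± 0.15). Neurog1 was at 4.55 ± 0.39 against 9.14 ± 0.17 (−4.59 ± 0.20, adjusted p = 1.25e-07), and Eomes was 4.79-fold lower (−2.26 ± 0.16). Fezf2, a determinant of deep-layer projection neurons, was lower by a log2 fold change of −3.59 ± 0.32. Fabp7, a radial glia marker, was 2.55-fold higher (1.35 ± 0.17, adjusted p = 0.000108).

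The median of all genes was −0.07 in this contrast, 0.04 with the values as deposited and −0.24 with arrays centred on their medians, so list medians are given relative to it. The basal progenitor list had 13 of 16 genes lower by either adjustment (median −2.05 relative to all genes, adjusted p = 3.98e-10, adjusted p = 0.0217 with an estimated correlation), with Nhlh1 5.79-fold lower. The interneuron list had 12 of 16 higher by either adjustment (median 1.58, adjusted p = 4.59e-12, adjusted p = 0.0382 with an estimated correlation). Among them, Gad1, the gene of a GABA-synthesising enzyme, was 8.16-fold higher and Lhx6 4.87-fold. All 19 G2/M genes were lower by either adjustment (median −1.52, adjusted p = 1.26e-14, adjusted p = 0.0382 with an estimated correlation), with Bub1b 5.96-fold lower. These 3 lists held with an estimated correlation.

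The other 10 called lists did not hold. Of the S-phase list 17 of 21 were lower, or 18 lower and 1 higher adjusted over the list alone (median −1.06, adjusted p = 8.08e-09, adjusted p = 0.0969 with an estimated correlation). The radial glia list had 14 of 22 lower and 4 higher by either adjustment (median −0.89, adjusted p = 0.000983, adjusted p = 0.263 with an estimated correlation). Ptprz1, a receptor phosphatase gene of radial glia and oligodendrocyte precursors, was among the higher at 4.44-fold. The Notch list had 11 of 19 lower and 1 higher, 13 and 1 adjusted over the list alone (median −0.71, adjusted p = 0.000386, adjusted p = 0.0969 with an estimated correlation), with Notch1 4.38-fold lower. Pallial patterning had 8 of 12 lower and 2 higher by either adjustment (median −1.67, adjusted p = 0.00118, adjusted p = 0.0969 with an estimated correlation), glycolysis 9 of 12 lower and 2 higher (median −1.02, adjusted p = 0.00283, adjusted p = 0.157 with an estimated correlation). Early temporal factors had 3 of 5 lower by either adjustment (median −1.15, adjusted p = 0.0253, adjusted p = 0.0969 with an estimated correlation), among them Hmga2 (−1.90 ± 0.17).

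Higher at E18 were 12 of 21 genes of the postmitotic neuron list, with 4 lower, 13 and 4 adjusted over the list alone (median 0.71, adjusted p = 0.000128, adjusted p = 0.0969 with an estimated correlation). Mapt was 5.57-fold higher, whereas Fezf2 was lower as given above. The astroglial maturation list had 10 of 21 higher and 2 lower, 11 and 2 adjusted over the list alone (median 0.64, adjusted p = 0.00140, adjusted p = 0.0969 with an estimated correlation). Tnc was 8.03-fold higher, and Gja1, a gap junction gene, 4.92-fold lower. The oligodendrocyte list had 3 of 11 higher and 1 lower, 4 and 1 adjusted over the list alone (median 0.33, adjusted p = 0.00521, adjusted p = 0.263 with an estimated correlation), with Olig2 at 7.92 ± 0.45 against 5.25 ± 0.54. Another of the 3, Pdgfra (7.59 ± 0.77 against 4.23 ± 0.17), turned to −0.63 with a pseudocount of 1 (adjusted p = 0.586). The call of the list ended without the dimmest 40% of genes (0.0644). The microglia list had 1 of 15 higher, the protease gene Ctss, and none adjusted over the list alone (median 0.50, adjusted p = 0.0439, adjusted p = 0.306 with an estimated correlation). The call of the microglia list ended without E14 replicate 1 (0.0523), 2 (0.0831) or 4 (0.0624), without E18 replicate 4 (0.0862) or 5 (0.0891), and without the dimmest 40% of genes (0.175). That of Ctss ended without E14 replicate 4 (0.0555) or E18 replicate 4 (0.0582) or 5 (0.0568). The 14 lists not called had medians from −0.44 to 0.14 before that subtraction and adjusted p from 0.0804 to 0.997, and in 6 of them the median, mean and test differed in sign.

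**Figure D4:**
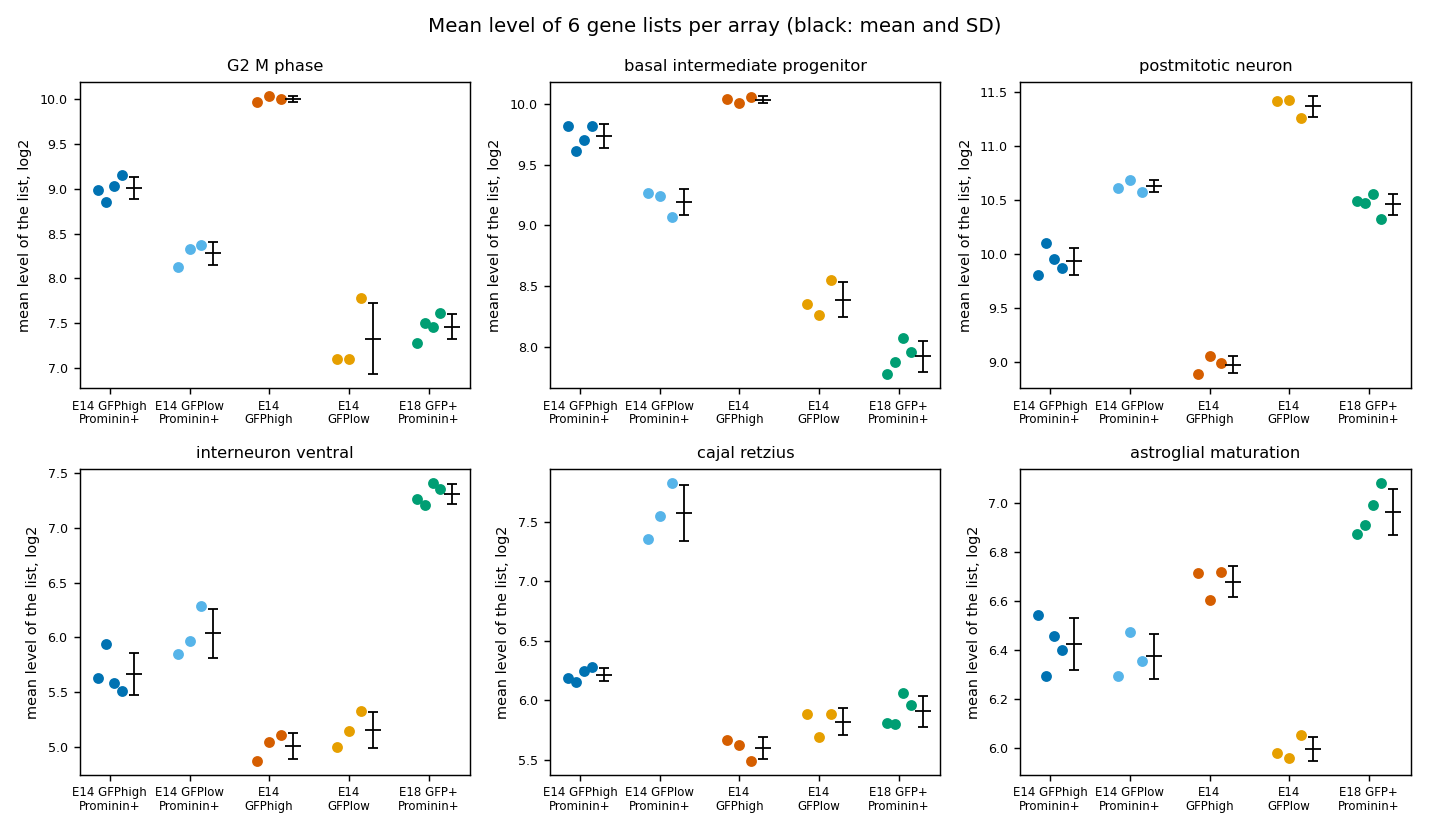
Mean log2 intensity of the genes of 6 lists on each of the 17 arrays in the 5 groups, with 1 point per array. The lists are G2/M, basal progenitor, postmitotic neuron, interneuron, Cajal-Retzius and astroglial maturation. The Cajal-Retzius list lies at 6.22 ± 0.06 in E14 GFP-high Prominin-selected cells and at 7.58 ± 0.24 in their GFP-low counterpart.

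From E14 GFP-high to E18 cells 4850 genes changed, 1850 higher (38.1%) and 3000 lower, and 1779 of them at least doubled or halved. At an unadjusted p under 0.05 there were 6595, and 29.0% of genes had groups that did not overlap, against 2.86% by chance. The share higher depended on the scaling, at 46.7% with the values as deposited and 21.3% with median centring. Of the 4850, 1627 (33.5%) changed in the opposite direction between gated and ungated E14 GFP-low cells, a contrast that shares no array with this one, and 178 in the same direction.

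The other E14 Prominin-selected group gave a further view of the change with age. Set against E14 GFP-low Prominin-selected cells, E18 cells had 2.55-fold less Prom1 mRNA (−1.35 ± 0.14, 8.84 ± 0.17 against 10.19 ± 0.08, adjusted p = 9.22e-05), with Gfap at 5.77 ± 0.37 and 5.10 ± 0.79 (adjusted p = 0.181). Olig1 was at 10.61 ± 0.31 at E18 against 5.07 ± 0.82 (5.54 ± 0.31, adjusted p = 1.91e-06). Gad1 was 5.85-fold higher (2.55 ± 0.26) and Tnc, a matrix glycoprotein gene of astroglia, 8.74-fold higher (3.13 ± 0.23). Fezf2 was 14.7-fold lower (−3.88 ± 0.34, 7.59 ± 0.78 against 11.47 ± 0.16, adjusted p = 2.81e-05), and Reln 3.58-fold lower (−1.84 ± 0.25, adjusted p = 0.000471), and Neurog1 was at 4.55 ± 0.39 against 7.66 ± 0.24 (−3.11 ± 0.21). Fabp7 was 3.36-fold higher (1.75 ± 0.19, adjusted p = 9.26e-05).

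The median of all genes was −0.10 here, −0.02 with the values as deposited and −0.23 with median centring, and list medians are relative to it. Held with an estimated correlation were 4 lists. Of the basal progenitor list 10 of 16 were lower, 12 adjusted over the list alone (median −1.43, adjusted p = 1.99e-07, adjusted p = 0.0275 with an estimated correlation). Of the Cajal-Retzius list 7 of 8 were lower, 8 adjusted over the list alone (median −1.62, adjusted p = 2.60e-07, adjusted p = 0.0275 with an estimated correlation), with Nhlh2 7.38-fold lower. The interneuron list had 11 of 16 higher by either adjustment (median 1.57, adjusted p = 2.22e-10, adjusted p = 0.0303 with an estimated correlation). The astroglial maturation list had 7 of 21 higher and 2 lower, 8 and 2 adjusted over the list alone (median 0.72, adjusted p = 3.54e-05, adjusted p = 0.0303 with an estimated correlation), with Gja1 2.60-fold lower. The other 10 did not hold. The G2/M list had 14 of 19 lower, 16 adjusted over the list alone (median −0.77, adjusted p = 2.47e-07, adjusted p = 0.0974 with an estimated correlation). The S-phase list had 8 of 21 lower and 1 higher, 14 and 1 adjusted over the list alone (median −0.43, adjusted p = 0.000651, adjusted p = 0.244 with an estimated correlation). Early temporal factors had 3 of 5 lower by either adjustment (median −0.97, adjusted p = 0.0247, adjusted p = 0.0974 with an estimated correlation), and Wnt genes 8 of 21 lower and 1 higher, 9 and 1 adjusted over the list alone (median −0.18, adjusted p = 0.00858, adjusted p = 0.0974 with an estimated correlation). The oligodendrocyte list had 3 of 11 higher, or 3 higher and 1 lower adjusted over the list alone (median 0.56, adjusted p = 0.000544, adjusted p = 0.216 with an estimated correlation). Of the 3, Pdgfra turned to −1.46 with a pseudocount of 1 (adjusted p = 0.233), and its call ended with the mean of a gene's probe sets (0.170). The matrix and receptor list had 7 of 19 higher and 2 lower, 7 and 3 adjusted over the list alone (median 0.17, adjusted p = 0.0340, adjusted p = 0.0974 with an estimated correlation).

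For the last 4 lists called against GFP-low cells, other settings also ended the call. Pallial patterning had 7 of 12 lower and 2 higher, 8 and 2 adjusted over the list alone (median −0.83, adjusted p = 0.0214, adjusted p = 0.218 with an estimated correlation). It ended without the dimmest 40% of genes (0.0877) and with the mean of a gene's probe sets (0.0653). The Notch list had 7 of 19 lower and 1 higher, 9 and 3 adjusted over the list alone (median −0.35, adjusted p = 0.0365, adjusted p = 0.254 with an estimated correlation). It ended without the dimmest genes (0.126) and without E14 replicate 3 (0.156). Glycolysis had 6 of 12 lower and 1 higher, 7 and 1 adjusted over the list alone (median −0.53, adjusted p = 0.0365, adjusted p = 0.254 with an estimated correlation). It ended without the dimmest genes (0.126) and without E14 replicate 2 (0.104). The microglia list had no gene of 15 past the threshold by either adjustment (median 0.45, adjusted p = 0.0365, adjusted p = 0.254 with an estimated correlation). It ended without the dimmest genes (0.401), with the mean of a gene's probe sets (0.0646), without E14 replicate 2 (0.0772) and without E18 replicate 4 (0.0789) or 5 (0.0948). The 13 lists not called had medians from −0.43 to 0.27 before that subtraction and adjusted p from 0.0641 to 0.912, and in 4 of them the median, mean and test differed in sign. In all, 3166 genes changed, 1095 higher (34.6%, 43.8% as deposited and 21.2% with median centring) and 2071 lower, and 1087 at least doubled or halved. At an unadjusted p under 0.05 there were 5511, and 28.8% of genes had groups that did not overlap, against 5.71% by chance. Of the 3166, 855 (27.0%) changed in the opposite direction between gated and ungated E14 GFP-high cells, and 328 in the same direction.

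To show what selection for Prominin goes with, gated and ungated cells were compared at equal GFP level. These contrasts coincide with the labelling kits, apart from ungated GFP-high replicate 1, and with the control signals given above. Every value with the kit in the fit rests on the kit label of that array. Its controls were close to those of ungated GFP-high replicate 3, which is labelled with the other kit, with Gapdh differences of −0.193 and −0.191 and bioB signals of 1132 and 1110, and the label could not be checked otherwise. In GFP-high cells, Prom1 was at 10.93 ± 0.09 with the gate and 10.79 ± 0.04 without (0.14 ± 0.15, adjusted p = 0.585), and Gfap at 5.42 ± 0.26 and 5.59 ± 0.36 (adjusted p = 0.781). The ribosomal protein gene Rpl27a was 9.52-fold higher in gated cells (3.25 ± 0.24, adjusted p = 4.40e-07), and Ina 7.63-fold higher (2.93 ± 0.25). Zfp612 was at 8.85 ± 0.37 against 5.38 ± 0.87 (3.47 ± 0.32). Pdia3, which encodes a protein folding enzyme, was 10.8-fold lower (−3.43 ± 0.32, adjusted p = 3.20e-06), and Mta2, which encodes a chromatin remodelling subunit, 8.91-fold lower (−3.16 ± 0.30). Fabp7 was 3.57-fold lower (−1.84 ± 0.19, adjusted p = 9.78e-06). Pax6 was 2.03-fold lower (−1.02 ± 0.23, adjusted p = 0.00393), a call that ended with the kit as a term in the fit (0.111).

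Of the postmitotic neuron list 12 of 21 genes were higher in gated GFP-high cells, 15 adjusted over the list alone (median 0.80, adjusted p = 6.13e-08, adjusted p = 0.0777 with an estimated correlation). Of the interneuron list 7 of 16 were higher, or 9 higher and 1 lower adjusted over the list alone (median 0.85, adjusted p = 0.0102, adjusted p = 0.204 with an estimated correlation). Lower were 14 of 21 S-phase genes, 15 adjusted over the list alone (median −1.02, adjusted p = 6.86e-11, adjusted p = 0.126 with an estimated correlation), and 13 of 19 G2/M genes, 15 adjusted over the list alone (median −1.04, adjusted p = 1.08e-10, adjusted p = 0.193 with an estimated correlation). Lower too were 12 of 22 radial glia genes, 14 adjusted over the list alone (median −0.87, adjusted p = 2.46e-08, adjusted p = 0.193 with an estimated correlation), with Ednrb at 7.86 ± 0.31 against 9.79 ± 0.09. The apical junction list had 8 of 15 lower and 1 higher by either adjustment (median −0.55, adjusted p = 0.0102, adjusted p = 0.312 with an estimated correlation). The 21 lists not called had medians from −0.79 to 0.64 and adjusted p from 0.0779 to 0.927, and in 5 of them the median, mean and test differed in sign. In total 3774 genes changed, 2141 higher (56.7%, 56.4% as deposited and 46.7% with median centring) and 1633 lower, and 1361 at least doubled or halved. At an unadjusted p under 0.05 there were 5855, and 30.6% of genes had groups that did not overlap, against 5.71% by chance. The count was 1688 with the kit as a term and 1661 when the ungated group was only the array labelled with the kit of the gated arrays, which has a meaning for the kit only if that label is right.

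In GFP-low cells, Prom1 was 2.94-fold higher with the gate than without (1.56 ± 0.16, 10.19 ± 0.08 against 8.63 ± 0.29, adjusted p = 2.37e-05), and Gfap was at 5.10 ± 0.79 and 4.82 ± 0.45 (adjusted p = 0.629). Reln was 9.04-fold higher in gated cells (3.18 ± 0.27, 11.82 ± 0.21 against 8.64 ± 0.41, adjusted p = 5.20e-06), and Rpl27a 9.30-fold higher (3.22 ± 0.26). Eomes was 3.30-fold higher (1.72 ± 0.20, adjusted p = 5.44e-05). Mapt was lower by a log2 fold change of −2.70 ± 0.22 (adjusted p = 3.95e-06), Tubb3, the gene of a neuronal tubulin, 3.49-fold lower (−1.80 ± 0.20), and Mta2 7.53-fold lower (−2.91 ± 0.32).

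Of the Cajal-Retzius list 7 of 8 genes were higher in gated GFP-low cells, 8 adjusted over the list alone (median 1.70, adjusted p = 9.44e-08, adjusted p = 0.00318 with an estimated correlation), among them Lhx1 (2.07 ± 0.33) and Ebf3 (1.71 ± 0.20). The basal progenitor list had 8 of 16 higher and 1 lower, 13 and 1 adjusted over the list alone (median 0.69, adjusted p = 2.80e-05, adjusted p = 0.0221 with an estimated correlation). The postmitotic neuron list had 11 of 21 lower and 2 higher, 13 and 2 adjusted over the list alone (median −0.66, adjusted p = 7.41e-07, adjusted p = 0.0410 with an estimated correlation). The other 6 lists did not hold with an estimated correlation. They were the G2/M list with 12 of 19 higher, 15 adjusted over the list alone (median 0.94, adjusted p = 4.12e-08, adjusted p = 0.187 with an estimated correlation), and the S-phase list with 10 of 21 by either adjustment (median 0.55, adjusted p = 2.80e-05, adjusted p = 0.224 with an estimated correlation). The radial glia list had 12 of 22 higher and 2 lower, 14 and 2 adjusted over the list alone (median 1.03, adjusted p = 0.000151, adjusted p = 0.301 with an estimated correlation), with the cadherin gene Cdh2 2.81-fold lower. The interneuron list had 8 of 16 higher, 9 adjusted over the list alone (median 0.77, adjusted p = 0.000151, adjusted p = 0.0856 with an estimated correlation). The pallial patterning list had 6 of 12 higher and 1 lower, 8 and 1 adjusted over the list alone (median 0.92, adjusted p = 0.000234, adjusted p = 0.187 with an estimated correlation). The Notch list had 6 of 19 higher and 2 lower, 10 and 2 adjusted over the list alone (median 0.54, adjusted p = 0.0127, adjusted p = 0.224 with an estimated correlation). The call of the Notch list ended without the dimmest 40% of genes (0.114), with the mean of a gene's probe sets (0.454) and without gated GFP-low replicate 3 (0.0506). The 18 lists not called had medians from −0.21 to 0.46 and adjusted p from 0.0692 to 0.975, and in 3 of them the median, mean and test differed in sign. In total 3496 genes changed, 1957 higher (56%, 58.1% as deposited and 37.5% with median centring) and 1539 lower, and 1434 at least doubled or halved. At an unadjusted p under 0.05 there were 5705, and 32.6% of genes had groups that did not overlap, against 10% by chance. The count was 1518 when only the arrays of these groups were fitted.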

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

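Tests chosen only after the result was seen were the comparison of Cajal-Retzius with other neuronal genes, the leave-outs read for the Cajal-Retzius list, the sign of that list in the difference of contrasts, and the scope of the outlier tests.

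The first pattern is the lower level of Cajal-Retzius genes in GFP-high Prominin-selected cells at E14, with Reln at 9.02 ± 0.23 against 11.82 ± 0.21 in GFP-low cells; 0 of the 8 genes are in another list, and 7 lie above the median gene level in the GFP-low group. RNA from Cajal-Retzius cells in the GFP-low sort, which a gate on Prominin would be meant to leave out, is a candidate explanation that stays open: 0 of 4 markers outside the list lay above the median gene level in either group, so that test was void. A higher share of neurons of every kind was not settled by permutation. The Cajal-Retzius list fell further than the postmitotic neuron list by 0.67 (exact two-sided permutation p = 0.0286, the smallest that 35 splits allow). Against the neuronal genes that fell by more than 2, 3 or 4 on the log2 scale without the gate, the difference was −0.33, −0.18 and 0.01 (exact p = 0.114, 0.400 and 1). In GFP-low cells the means of these lists moved in opposite directions with the gate, which this explanation alone would not give. The postmitotic neuron list was higher in ungated than in gated GFP-low cells (11.37 ± 0.09 against 10.63 ± 0.06). The Cajal-Retzius list was lower in the ungated cells (5.82 ± 0.11 against 7.58 ± 0.24). Gated and ungated arrays also differ in kit and control signals, so these means, which were not a planned test, do not decide the question. A cause in 1 array alone is argued against, as the highest adjusted p of the list with any array left out was 1.43e-10. Expression of these genes by GFP-low Prominin-selected progenitors is a biological explanation that was not tested.

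The second pattern is the larger GFP contrast without the Prominin gate, in which 1400 genes differed. The labelling kit of ungated GFP-high replicate 1 is argued against as its cause. Over the 305 genes called with the gate, the slope of the ungated on the gated contrast was 2.00 without that array and 2.01 with it. Without that array the gated and ungated arrays still differ throughout in the labelled kit and in control signals, which this slope does not cover. A single factor shrinking every fold change on the Prominin-selected arrays is argued against for the whole pattern, since the Cajal-Retzius list had a larger fall with the gate (median of the difference −0.91). A gate that removes neurons and cells without Prominin from the GFP-low sort may account for part of the pattern. This biological explanation was not tested. In GFP-low cells the mean of the postmitotic neuron list was lower with the gate (10.63 ± 0.06 against 11.37 ± 0.09). In GFP-high cells it was higher with the gate (9.93 ± 0.13 against 8.98 ± 0.08), and that of the radial glia list lower (9.66 ± 0.17 against 10.51 ± 0.03). Removal from the GFP-low sort does not cover these differences in GFP-high cells.

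The third pattern is the set of genes that parts the E14 Prominin-selected arrays from all others. A preparation difference of these arrays is consistent with it: 74.7% of 1606 genes that changed between gated and ungated GFP-low cells had the opposite sign from E14 GFP-high to E18 cells, and 76.4% of 1812 genes that changed at high GFP did so from GFP-low to E18 cells. These are only the genes, of 3496 and 3774 changed, whose log2 fold change between ungated GFP-high and GFP-low cells was within 0.5. The labelling kit as the labels name it was not settled as a cause. Positions were read on an axis from ungated GFP-low cells at 0 to Prominin-selected GFP-low cells at 1. The E18 arrays, labelled with the kit of the E14 Prominin-selected arrays, lay at 0.475 to 0.649. Ungated GFP-high replicate 1 carries the same kit label and lay at 0.08, against 0.184 and 0.047 for the rest of its group. The labelled kit alone therefore did not place these arrays at 1. However, age also differs at E18, and the label of the lone ungated array may be wrong. Age remains an open, untested biological explanation for the genes that differ between E14 and E18.

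Other splits of the same arrays were counted for each comparison. Chance is argued against for the gated GFP contrast, where only the real split (1 of 35) gave 305 genes and the highest other gave 4. The same holds for E18 against GFP-high cells (1 of 35, 4850 against 1) and E18 against GFP-low cells (1 of 35, 3166 against 397). It holds too for gated against ungated GFP-high cells (1 of 35, 3774 against 1494). A share of 1 in 35 is 0.0286, the smallest possible here, and it was not adjusted over the 7 comparisons. The 10 splits of the ungated GFP contrast (1 as large, 2869 against 0) and of gated against ungated GFP-low cells (1 as large, 3496 against 0) are too few for a share under 0.05. For the difference of contrasts 9 of 100 drawn splits gave a count of 1400 or more, with 3546 the highest. These 9 were all the drawn splits that parted the ungated arrays as labelled or mirrored, and the highest of the rest was 2. Such a split keeps the ungated GFP contrast whole, however the gated arrays are parted. The count therefore could not test chance for the difference of contrasts, and chance is not excluded by it.

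In the difference of contrasts, the test of the difference itself also set apart these list medians: radial glia −1.59, basal progenitor −1.10, postmitotic neuron 1.54, astroglial maturation −0.45, S phase −1.71, G2/M −1.94, Notch −0.80, apical junction −0.38 and pallial patterning −1.17. Among genes, the difference was positive for Sla (3.82), Mapt (3.65), Plk2 (3.55), Lrfn5 (3.52), Ina (3.46) and Tubb3 (1.54), whose fall without the gate was larger. It was negative for Prom1 (−1.42), Fabp7 (−1.49), Tfap2c (−1.65), Eomes (−1.76), Pax6 (−2.22), Calb2 (−2.56), Arhgap11a (−2.62), Tk1 (−2.66), Cxcr4 (−2.71) and Cip2a (−2.79). Without the 4 doubted arrays the calls of Fabp7 (adjusted p = 0.0858), Tfap2c (0.0525), Tk1 (0.0552) and Cxcr4 (0.0637) ended, and that of Cip2a ended with the mean of its probe sets (0.175).

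Single arrays lay far from the others of their group in 14 of 144 tests, 9.72%, where chance gives about 1 in 20. Among E14 GFP-high Prominin-selected arrays, replicate 1 stood apart in the levels of Fezf2 (11.63), Mfap4 (9.73), Slc1a3 (7.68) and Tafa2 (4.78). It did so too in the 3′ minus 5′ difference of Gapdh (0.54) and Actb (0.89). Replicate 2 stood apart in Pawr (6.07) and in its median signal (39.0), and replicate 4 in Eomes (12.11) and the mean of the S-phase list (9.15). At E18, replicate 3 stood apart in Tcf7l1 (5.98) and in the dap control (1054), and replicate 2 in the mean of the endothelial list (4.89). The dap poly-A control, which lies outside the gene comparisons, read 4085 on E14 GFP-high Prominin-selected replicate 1 against 3.85 to 22.3 on the other 6 E14 Prominin-selected arrays.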

How the results depend on the processing

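The alternatives that left out 2 or 4 doubted arrays were chosen after the results were seen, and the others were planned. The gated GFP contrast at E14 moved most, and unless the construction of an alternative shows it, the cause was not tested. Its 305 genes became 109 with median centring, 74 and 554 with pseudocounts of 1 and 64, 510 without the dimmest 40% of genes, 143 with the mean of a gene's probe sets, 154 probe sets tested by themselves, 466 with an intensity trend, 130 at a log2 fold change of at least 1, 58 when only its 2 groups were fitted and 6 without 2 doubted arrays. It was 265 with values as deposited, 274 with robust eBayes, 422 with array weights and 283 with all 17 arrays fitted. Signal over background limits dim genes most: the level of Gfap lay below the median gene level in every group, and the pseudocount shrinks fold changes most for such genes.

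Without 2 doubted arrays the ungated GFP contrast gave 1257 genes, and without 4 the difference of contrasts gave 597. Tested by themselves, 9906, 7384, 8300 and 7380 probe sets changed for E18 against GFP-high cells, E18 against GFP-low cells, and gated against ungated cells at high and at low GFP, where more features were tested. At a log2 fold change of at least 1 these were 1779, 1087, 1361 and 1434 genes, a subset by construction. Gated against ungated GFP-high cells gave 1688 with the kit as a term and 1661 with only the ungated array labelled with the same kit, a label that may be wrong, and gated against ungated GFP-low cells gave 1518 when only these groups were fitted. For the ungated GFP contrast that fit is the one reported. With an estimated correlation the called lists numbered 0 in the ungated GFP contrast, 3 and 4 for E18 against GFP-high and GFP-low cells, and 0 and 3 for gated against ungated cells at high and low GFP. In the comparisons with 0, camera gave 8 and 6 lists at an unadjusted p under 0.05. The mean of a gene's probe sets gave 11 lists for gated against ungated GFP-high cells.

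Directions reversed for a few named genes. With a pseudocount of 1, Pdgfra was −0.63 at E18 against GFP-high cells and −1.46 against GFP-low cells, and Foxc1 was 0.71 between gated and ungated GFP-low cells. With the mean of a gene's probe sets, Vcan was −0.0206 at E18 against GFP-high cells and Pax6 0.0616 against GFP-low cells. Ncan was −0.0310 between gated and ungated GFP-high cells, and Pax6 −0.160, Numb −0.0204 and Slc1a3 −0.180 between gated and ungated GFP-low cells.

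With the replicate number as a replicate block, limma called 0 genes in the gated GFP contrast (1413 at an unadjusted p under 0.05), 1867 in the ungated one, 3114 and 0 (3362 at an unadjusted p under 0.05) for E18 against GFP-high and GFP-low cells, and 1466 and 42 for gated against ungated cells at high and low GFP. Arrays with the same number showed correlations of only −0.144 to 0.040 after group means were removed. Whether equal numbers mark a shared source is not known from the labels. If they do not, the block spends degrees of freedom for no gain. Either way it drops from the contrast every array without a partner of the same number. E18 against GFP-low cells then rests on replicates 2 and 3 of each group, and the gated GFP contrast loses GFP-high replicate 4.

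Leaving out each array in turn gave 76 to 228 genes and 8 to 12 lists in the gated GFP contrast, 1841 (without GFP-high replicate 1) to 2854 and 10 to 13 in the ungated one, 4028 to 4599 and 12 to 13 for E18 against GFP-high cells, and 2286 to 3056 and 12 to 15 against GFP-low cells. For gated against ungated cells it gave 2775 to 3519 and 6 to 7 at high GFP and 2420 to 3817 and 9 to 10 at low GFP, and it gave 1033 to 1729 and 10 to 11 for the difference of contrasts. Of the named genes called, 4 of 43, 65 of 81, 81 of 95, 62 of 80, 52 of 81, 55 of 78 and 44 of 70, in the same order, kept their call in every alternative other than the replicate block, and those 4 were Reln, Rspo3, Dact1 and Dsp.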

Other observations

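No test in this part was chosen after the result was seen. Of the immediate early and stress genes, Egr1 was 9.77-fold higher in Prominin-selected than in ungated GFP-low cells (log2 fold change 3.29 ± 0.70, adjusted p = 0.00352, n = 3 against 3). Fos, another gene switched on within minutes of a stimulus, was 3.17-fold higher (1.66 ± 0.39, 11.32 ± 0.35 against 9.66 ± 0.56, adjusted p = 0.00646). Of the 16 genes of the list 4 rose and none fell by either adjustment, and the list itself was not called (median 0.46, adjusted p = 0.0692). In E18 cells the mean level of the list spread over 7.14 to 8.27, with an SD of 0.60.

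Mean levels of lists for other cell types were compared with the median of 6.29 for all genes. Over the 5 groups, that of the endothelial list was 5.05 to 5.17, that of the choroid plexus and hem list 4.87 to 5.07, that of the pericyte and meninges list 4.78 to 5.03, that of the erythroid list 4.88 to 5.19 and that of the microglia list 4.94 to 5.33. Single members were higher, such as the embryonic globin gene Hbb-y at 8.23 ± 1.47 in E14 GFP-low Prominin-selected cells. The interneuron list reached 7.31 ± 0.09 and the oligodendrocyte list 6.57 ± 0.41 at E18. The gliogenic list, with factors of astrocyte and oligodendrocyte formation, lay at 8.81 ± 0.09 in E14 GFP-high and 8.54 ± 0.06 in GFP-low Prominin-selected cells, 8.75 ± 0.03 in ungated GFP-high and 8.29 ± 0.12 in ungated GFP-low cells, and 9.02 ± 0.11 at E18. It was not called in any comparison.

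The Y-linked gene Eif2s3y was between 6.46 and 8.24 on every array. Xist, the transcript of the inactive X chromosome, was at 8.17 to 9.19 on the ungated arrays, 9.81 to 11.2 on the E14 Prominin-selected arrays and 12.5 to 12.9 at E18. The 4 leading principal components of the arrays held 29.5%, 18.5%, 13.4% and 5.20% of the variance, and E14 GFP-low Prominin-selected replicate 3 lay apart on the fourth component, at −51.3. The highest correlation between a pair of arrays was 0.983 and the lowest 0.885.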
